A study of Mus musculus with 17 samples.

How the data were processed

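RNA was measured in P14 CD8+ T cells, which carry a T cell receptor specific for lymphocytic choriomeningitis virus Armstrong, at day 32 after infection of mice. Per the labels' protocols, splenocytes were left undigested or were held for 30 minutes in collagenase at 37 °C, in dithioerythritol (DTE) at 37 °C or in a cold active protease (CAP) at 4 °C. Kidney was digested in collagenase or CAP in the same way, and each sample was pooled from 4 to 6 mice. Libraries were made with Smart-seq2 from polyA RNA at ultra-low input, a method that does not mark the strand. Overlapping and antisense genes were therefore not told apart.

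Per the submitters' processing notes, the authors used Trimmomatic 0.38, STAR 2.5.2b, featureCounts 1.5.3 and DESeq2 1.3.2 with the mm10 genome build. The annotation release was not stated. The deposited raw table holds whole-number counts per gene for 55401 genes in 12 libraries. The deposited normalized table holds a signal that equals each count times 1 constant per library plus 1, as checked on the values. It was used only for that check. Gene symbols were taken from the table itself. Of its versioned gene identifiers, 54349 were in GENCODE M21 (GRCm38) with the same version and 55141 when the version was ignored. Coordinates are from that annotation, counted from 1.

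The labels describe 17 samples in 6 groups. Counts for 12 of them were analysed, 2 per group, and the other 5 were not used here. Columns were numbered 1 and 3 within each group. A kidney CAP column had a number that no kidney CAP sample carries, so it was assigned to its group alone and is called the unnumbered library. Total counts per library ran from 1199423 to 2700518, with a median of 2331404.5. Tested genes held 98.5% to 99.4% of these counts.

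Genes were tested with edgeR 4.0.16 in R 4.3.3 on the raw counts. The filter was filterByExpr with its default minimum count of 10 and minimum total count of 15, which kept 11329 genes. Scaling was by trimmed mean of M values (TMM). All 12 libraries entered 1 model with 1 mean per group, fitted by robust quasi-likelihood, with 6 residual degrees of freedom. The common biological coefficient of variation was 0.397. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the genes of a comparison, and genes at an adjusted p under 0.05 were counted by direction. A further count required an absolute log2 fold change over 1. Levels are counts scaled to 1e+06 per library (CPM) on the TMM-scaled library size, as mean ± SD. Fold changes are given ± SE on the log2 scale.

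The 9 comparisons were each spleen treatment against undigested spleen, collagenase against CAP and against DTE in spleen, collagenase against CAP in kidney, kidney against spleen in each enzyme, and the interaction of tissue and digestion. The tests, the 23 gene lists and the rule for naming genes were set before the data were examined. The rule named, per comparison, up to 6 higher and 6 lower genes with the largest changes among those past the threshold whose groups did not overlap and whose higher group reached 10 CPM, without predicted genes. It added up to 3 called members of each list with the smallest p, and a fixed panel of Fos, Jun, Egr1, Nr4a1, Dusp1, Hspa1a, Cd69, Itgae, Itga1, Cxcr6, Xcl1, Klf2, S1pr1 and a gene that is not reported here. With fewer than 20 called genes in a comparison, any of them could be named.

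Of 368 different list genes, 366 were in the table. Lists with at least 3 tested members, 20 of them, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. List members were also counted with p-values adjusted over the list alone. A group without counts was set at a floor of 3 counts over the group, which makes its fold a lower bound. With 1 to 3 counts a ratio is given with its 95% exact interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The p-values measure only the spread between these samples.

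Composition measures were compared by two-sided exact permutation tests, which cannot go below p = 0.333 with 2 libraries per group. The model was tested on simulated counts with 200 genes changed by known folds per comparison. The changed genes were drawn only from those above a minimum mean level, so recovery of genes at low levels was not measured. Genes were simulated independently of each other. For collagenase against undigested spleen, it recovered 0 of 50 genes changed 2-fold, 19 of 50 changed 4-fold, 35 of 50 changed 8-fold and 46 of 50 changed 32-fold, among 10731 simulated genes. Comparisons that share the undigested libraries were set beside 40 simulations of unchanged groups.

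Alternatives were DESeq2-style size factors in edgeR, no filter on low counts, a filter at 10 CPM in 3 libraries, the replicate number as a block, DESeq2 1.42.0's Wald test, a fit of only the groups compared, and leaving out each library. Added later were the level of Gm10800 as a covariate and a fit without the counts of CT010467.1, mt-Rnr2, Gm10800 and Gm10801.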

Results

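The data asked what tissue digestion does to the RNA of memory CD8+ T cells, and which differences between kidney and spleen remain when both tissues are digested alike. Spleen cells come free without an enzyme, so an undigested group served as the background for collagenase, DTE and CAP. Kidney cells, taken as those that an antibody injected into the blood had not labelled, exist only as digested groups. Each of the 6 groups had 2 libraries with counts, each pooled from 4 to 6 mice. The labels do not say whether the pools of 1 group came from separate mice or days, so the SD and p-values measure the spread between samples of unknown independence. Total counts were 2325578 and 2343440 in undigested spleen, 1835542 and 1905932 in spleen collagenase, 1499682 and 2513208 in spleen DTE, and 2337231 and 2499188 in spleen CAP. They were 1733337 and 2339565 in kidney collagenase, and 1199423 and 2700518 in kidney CAP. Between 17495 and 22076 genes had counts in a library. All levels below are CPM as mean ± SD with n = 2.

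The NR4A nuclear receptors, which T cells induce within minutes of antigen receptor signalling, rose in spleen cells held in collagenase at 37 °C. Nr4a1 (chromosome 15, 101254269 to 101274795) went from 8.9 ± 10.7 CPM in undigested cells to 3150.1 ± 50.5 CPM, a log2 fold change of 8.45 ± 0.99. Nr4a2 rose by 8.27 ± 1.00 and Nr4a3 by 6.41 ± 0.75 on the log2 scale. Fosl2, a subunit of the AP-1 transcription factor, rose from 23.3 ± 8.23 to 681 ± 104 CPM. Its adjusted p was 0.000558 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cdkn1a, the cell cycle inhibitor p21, rose from 1.08 ± 0.261 to 118 ± 19.1 CPM. Heat shock genes rose too, with Hspa1a at 5.27 ± 7.46 CPM before and 1137 ± 888 CPM after, a log2 fold change of 7.72 ± 1.56. Reads of Hspa1a and its near-identical neighbour Hspa1b cannot be split with certainty. The co-chaperones Dnajb1 and Dnajb4 rose by 3.90 ± 0.72 and 2.55 ± 0.47. Among inhibitors and targets of NF-kB, Tnfaip3 rose by 4.57 ± 0.85, Nfkbiz by 4.28 ± 0.61 and Nfkbid by 2.64 ± 0.42. Egr1 rose by 3.62 ± 0.70, and Atf3 was higher by a ratio of 155 (52.5 to 753) over 1 to 3 counts. Rgs16 was at least 31.1-fold higher. Cd69 (chromosome 6, 129267325 to 129275436), a surface marker used to recognise resident memory cells, rose from 155 ± 14.3 to 942 ± 379 CPM with an adjusted p of 0.047. Crem and Skil, which are also counted among resident memory genes, rose by 4.26 ± 0.55 and 2.51 ± 0.41.

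In all, 82 of 11329 genes differed between spleen collagenase and undigested spleen, 81 higher and 1 lower. Every one of the 82 also changed by more than 1 on the log2 scale. Jun (3.79 ± 1.32), Dusp1 (3.09 ± 1.10) and Fos (2.61 ± 1.33) did not pass, with adjusted p of 0.358, 0.38 and 0.668. Their undigested libraries differed, with Fos at 71.7 CPM in replicate 1 and 0 in replicate 3. Jun passed without undigested replicate 1, with an adjusted p of 0.0109. Genes of circulating cells did not pass. S1pr1 changed by 0.02 ± 0.45 (adjusted p = 0.993) and Klf2 by 0.26 ± 0.67 (0.915). Cxcr6 at -1.53 ± 0.58, Xcl1 at 0.88 ± 0.73, Itgae at 0.36 ± 0.70 and Itga1 at -0.23 ± 0.58 did not pass either. Leaving out 1 library lowered the count to 30 without undigested replicate 1, 7 without undigested replicate 3, 26 without collagenase replicate 1 and 31 without collagenase replicate 3. Nr4a1, Nr4a2, Nr4a3, Fosl2 and Cdkn1a passed in each of those fits. Cd69 passed in none, with adjusted p of 0.21, 0.51, 0.0767 and 0.352 in the same order. Nor did Hspa1a (0.0671, 0.303, 0.157 and 0.0675), Egr1 (0.0872, 0.398, 0.205 and 0.0522), Atf3 (0.169, 0.174, 0.0885 and 0.059), Rgs16 (0.144, 0.221, 0.0517 and 0.0987), Dnajb4 (0.152, 0.294, 0.164 and 0.0522) or Skil (0.131, 0.149, 0.0517 and 0.0783). Without undigested replicate 3, Dnajb1 had 0.316, Tnfaip3 0.283, Nfkbid 0.203, Nfkbiz 0.128 and Crem 0.076. Dnajb1 and Nfkbid had 0.0671 and 0.0761 without undigested replicate 1, and 0.155 and 0.074 without collagenase replicate 1. Tnfaip3 had 0.118 without collagenase replicate 1 and 0.0521 without collagenase replicate 3. With all libraries, Cd69 had 0.0568 with DESeq2-style size factors, 0.0503 with the stricter filter and 0.0501 without CT010467.1, mt-Rnr2, Gm10800 and Gm10801. Hspa1a had 1 without a filter, 0.0503 with the stricter filter and 0.344 with the Gm10800 covariate, under which Atf3 had 0.111, Dnajb1 0.073 and Egr1 0.0619.

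Of the 20 gene lists tested, 6 were called by camera, all higher, and 3 of these held with an estimated correlation. Of 30 immediate early genes, 13 passed and 24 rose with p-values adjusted over the list alone, while 1, Ier3, fell. The list median was 3.26 (camera adjusted p = 8.06e-51). Of 18 heat shock genes, 4 passed and 13 rose adjusted over the list alone, with a median of 2.31. Their camera adjusted p of 3.09e-19 became adjusted p = 0.0731 with an estimated correlation. Among 15 NF-kB targets, 3 passed and 12 rose adjusted over the list alone (median 1.77, camera adjusted p = 3.26e-18). The resident memory list rose by a median of 0.96 in cells from spleen (camera adjusted p = 5.53e-14). Of its 27 tested genes, 8 passed (Nr4a1, Crem, Skil, Rgs2, Ctla4, Icos, Litaf and Cd69), and 11 rose and 1 fell adjusted over the list alone. Nr4a1 is also an immediate early gene and Skil also a TGF-beta response gene. The immediate early, NF-kB and resident memory calls held with an estimated correlation. TGF-beta response genes had a median of 0.85, with 2 of 11 passing and 3 adjusted over the list alone (camera adjusted p = 3.35e-06, adjusted p = 0.0731 with an estimated correlation). The unfolded protein response had a median of 0.48, with 0 of 19 passing and 3 adjusted over the list alone (camera adjusted p = 0.00176, adjusted p = 0.0731 with an estimated correlation).

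**Figure D1:**
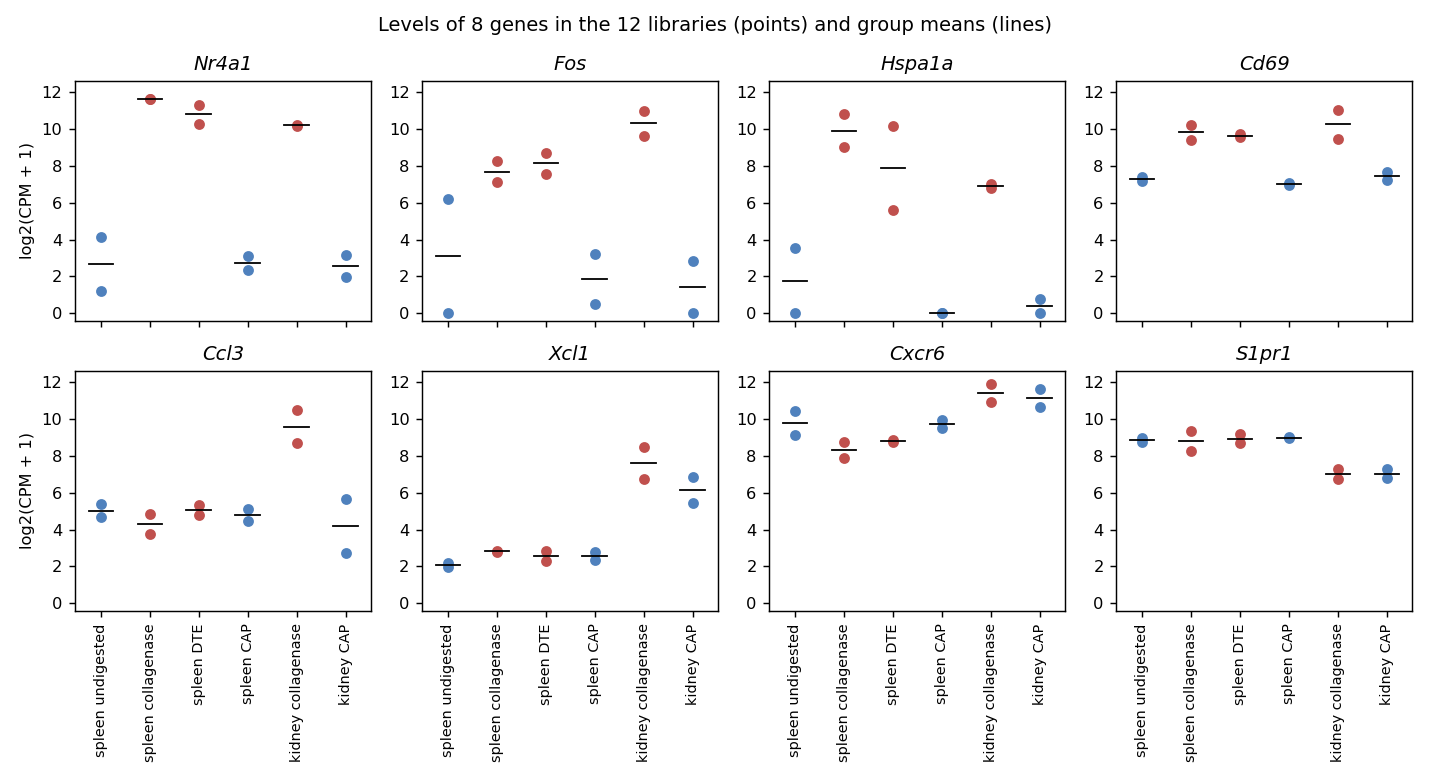
Levels of 8 genes as log2(CPM + 1) on the vertical axis, with each of the 12 libraries as a point, group means as lines, groups at 37 °C in red and the others in blue. Nr4a1 is at 3150.1 CPM on average in spleen collagenase and 8.9 CPM in undigested spleen, while Xcl1 separates by tissue.

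DTE, a reducing agent used to free cells from epithelium, raised much the same genes at 37 °C although it holds no enzyme. Nr4a1 rose to 1896.9 ± 928 CPM (log2 7.72 ± 0.96), Nr4a2 to 216 ± 31.2 CPM (6.76 ± 0.96) and Nr4a3 to 317 ± 102 CPM (5.74 ± 0.73). Cdkn1a reached 142 ± 116 CPM, a change of 6.96 ± 0.78. Fosl2 rose by 3.59 ± 0.46, Sik1 by 4.70 ± 0.63 and Egr1 by 4.79 ± 0.73. Nfkbid, Nfkbiz and Crem rose by 2.83 ± 0.42, 3.42 ± 0.59 and 2.79 ± 0.52. In total 25 genes passed, all higher. Cd69 at 788 ± 61.8 CPM (2.34 ± 0.54, adjusted p = 0.167) and Hspa1a at 602 ± 784 CPM (6.81 ± 1.51, adjusted p = 0.154) did not. Cxcr6 (-1.11 ± 0.58) and S1pr1 (0.08 ± 0.45) did not pass. The count of 25 became 9 without undigested replicate 1, 0 without undigested replicate 3, 8 without DTE replicate 1 and 16 without DTE replicate 3. Nr4a1 had an adjusted p of 0.0551 without undigested replicate 3. Hspa1a passed without DTE replicate 3 (0.027), and Jun without undigested replicate 1 (0.0239). Without undigested replicate 1, Nr4a3, Egr1 and Nfkbiz had 0.0578 each, Nfkbid 0.0888 and Crem 0.201. Without DTE replicate 1, Nfkbiz had 0.0547, Egr1 0.0861, Nfkbid 0.124 and Crem 0.461, and without DTE replicate 3 Crem had 0.0894 and Nfkbiz 0.185. Crem had 0.0502 with DESeq2-style size factors.

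Immediate early genes rose by a median of 3.13 in DTE, with 10 of 30 passing and 24 adjusted over the list alone (camera adjusted p = 3.99e-76). NF-kB targets (median 0.98, 2 of 15 passing, 4 adjusted over the list alone) and resident memory genes (median 0.36, 2 of 27 passing, 6 adjusted over the list alone) rose with camera adjusted p of 1e-13 and 2.98e-09. Those 3 calls held with an estimated correlation. Heat shock genes rose by a median of 1.15 with 0 of 18 passing and 6 adjusted over the list alone (camera adjusted p = 3.24e-13, adjusted p = 0.184 with an estimated correlation). Among cytokines the median was 0.73 with 0 of 10 passing, and Tnf, Ifng and Tnfsf9 rose adjusted over the list alone (camera adjusted p = 0.000134, adjusted p = 0.263 with an estimated correlation). The unfolded protein response (median 0.41) had 2 genes adjusted over the list alone and a camera adjusted p of 0.000565, adjusted p = 0.0856 with an estimated correlation. TGF-beta response genes (median 0.35) had 1 gene adjusted over the list alone and a camera adjusted p of 0.0158, adjusted p = 0.308 with an estimated correlation. Natural killer markers (median -1.08) and myeloid markers (median -0.71) were lower by camera at 0.0134 and 0.0158. These became adjusted p = 0.232 and adjusted p = 0.672 with an estimated correlation, and the myeloid list changed sign without undigested replicate 3 (0.572).

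Spleen cells kept in CAP at 4 °C differed from undigested cells in 0 genes by edgeR and 0 by DESeq2, and 90 genes had an unadjusted p under 0.05 where chance gives 566. Nr4a1 stood at 5.86 ± 2.43 CPM against 8.9 ± 10.7 CPM, a log2 change of -0.61 with a 95% interval from -2.38 to 1.17. Cd69 was at 129 ± 7.42 CPM against 155 ± 14.3 CPM (-0.27, interval -1.39 to 0.85). S1pr1 (0.11 ± 0.45), Cxcr6 (-0.17 ± 0.57) and Egr1 (-0.43 ± 0.73) lay close to 0. Fos (-3.04 ± 1.48), Jun (-3.11 ± 1.37) and Hspa1a, at 0 CPM in CAP, had lower estimates that did not pass, all against undigested libraries of which only replicate 1 had counts. In simulated counts for this comparison the test recovered 14 of 50 genes changed 4-fold, 33 of 50 changed 8-fold and 48 of 50 changed 32-fold, among 10799 genes. B cell markers were higher in CAP by a median of 0.64 (camera adjusted p = 1.69e-07, held with an estimated correlation), and Cd79a and Ighd passed adjusted over the list alone while 0 of 8 passed over all genes. Cell cycle genes were lower by a median of -0.84, with Top2a adjusted over the list alone (camera adjusted p = 9.54e-06, adjusted p = 0.0908 with an estimated correlation). Immediate early genes had a median of -0.36 and a camera adjusted p of 0.19. Without undigested replicate 1 that list was called higher in CAP, at 0.00521, and without undigested replicate 3 it was called lower, at 1.5e-08. Without undigested replicate 3 the myeloid list changed from 0.506 to 0.0123 with the opposite sign.

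The genes raised by collagenase and DTE were then compared. All 25 genes raised by DTE were among the 81 raised by collagenase, where independent lists share 0.179 and simulated unchanged groups at most 1. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.725 against a simulated median of 0.489. The covariance was 0.587 against 0.243, a difference of 0.344. Part of the excess in shared calls may come from the shared controls, since the simulated groups held no effects. The 25 became 9 without undigested replicate 1, 0 without undigested replicate 3, 8 without DTE replicate 1, and 15 without collagenase replicate 1, without collagenase replicate 3 or without DTE replicate 3. The correlation was 0.454 without collagenase replicate 1. For collagenase with CAP the covariance of 0.101 lay below the simulated 0.239 (correlations 0.173 and 0.495), and for DTE with CAP it was 0.139 against 0.240 (0.283 and 0.496). The observed correlations of collagenase and DTE with CAP became 0.665 and 0.716 without undigested replicate 1, 0.417 and 0.551 without undigested replicate 3, and 0.0654 and 0.162 without CAP replicate 1. No unchanged groups were simulated for those fits.

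**Figure D2:**
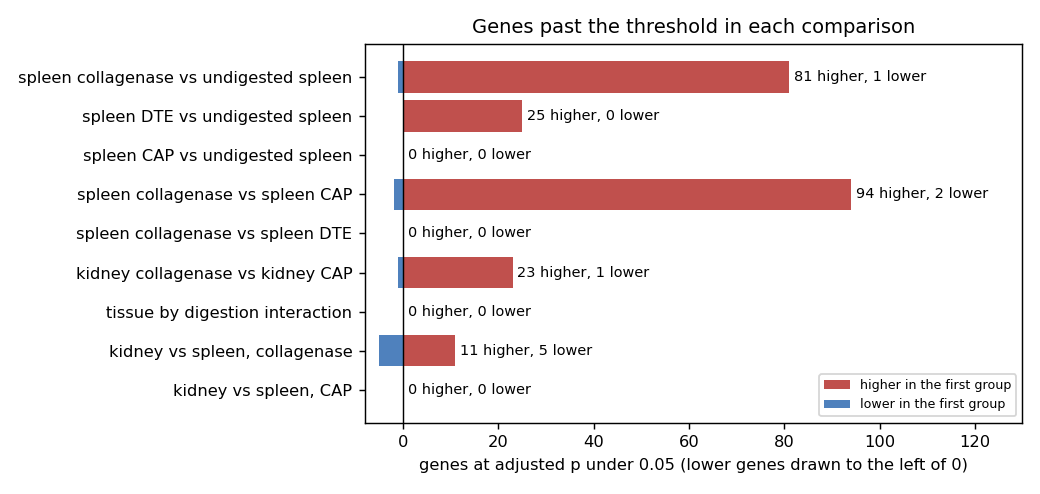
Number of genes at an adjusted p under 0.05 in each of the 9 comparisons on the horizontal axis, with genes higher in the group named first in red and lower genes in blue to the left of 0. Collagenase against CAP in spleen gives 94 higher and 2 lower genes, and CAP against undigested spleen gives 0.

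Warm digestion in collagenase and cold digestion in CAP were then compared directly, first in spleen. Collagenase was used only warm and CAP only cold, so effects of temperature and of enzyme cannot be told apart in this comparison. Nr4a1 was at 3150.1 ± 50.5 CPM in collagenase and 5.86 ± 2.43 CPM in CAP (9.05 ± 1.02). Nr4a2 (9.47 ± 1.09), Sik1 (6.93 ± 0.73), Tnfaip3 (5.99 ± 0.92), Fosl2 (4.96 ± 0.49), Crem (4.35 ± 0.55) and Nfkbiz (4.02 ± 0.60) were higher as well. Hspa1a and Hspa1b, which had no counts in CAP, were at least 1885-fold and at least 459-fold higher, with the split between them uncertain. Atf3 was at least 165-fold and Slc16a10 at least 43.6-fold higher. Dnajb1 rose by 4.12 ± 0.73, Egr1 by 4.06 ± 0.72, Nfkbid by 2.90 ± 0.43, Dnajb4 by 2.68 ± 0.47 and Skil by 2.61 ± 0.42. Cd69 was higher by 2.87 ± 0.55 (942 ± 379 against 129 ± 7.42 CPM, adjusted p = 0.0246). Serpinb9, an inhibitor of granzyme B, was higher by 2.82 ± 0.61 (adjusted p = 0.0485). Serpinb9 had 0.382 without collagenase replicate 3, 0.385 without CAP replicate 1, 0.64 without CAP replicate 3 and 0.0654 with the Gm10800 covariate. The zinc finger gene Zfp273 was lower in collagenase by a ratio of 22 (5.82 to 186) over low counts (adjusted p = 0.0451).

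Collagenase against CAP in spleen gave 96 genes, 94 higher and 2 lower. That count became 47 without collagenase replicate 1, 48 without collagenase replicate 3, 11 without CAP replicate 1 and 6 without CAP replicate 3. Fosl2, Sik1, Nr4a1 and Nr4a2 passed in all of those, while Cd69 had an adjusted p of 0.174 without collagenase replicate 3, 0.371 without CAP replicate 1 and 0.476 without CAP replicate 3. In the fits without CAP replicate 1 and without CAP replicate 3, Hspa1a had 0.173 and 0.188 and Egr1 0.198 and 0.356, and Egr1 had 0.103 without collagenase replicate 1. Tnfaip3, Crem, Nfkbiz, Hspa1b, Atf3, Slc16a10, Dnajb1, Nfkbid, Dnajb4 and Skil had between 0.0682 and 0.282 without CAP replicate 1, and between 0.116 and 0.366 without CAP replicate 3. Without collagenase replicate 1, Dnajb1 had 0.0993, Dnajb4 and Hspa1b 0.112 each and Slc16a10 0.14, and without collagenase replicate 3 Skil had 0.0543. Zfp273 passed in none of the 4 fits (0.318, 0.262, 0.409 and 0.137). With the Gm10800 covariate, Hspa1a had 0.286, Hspa1b 0.464, Atf3 0.0814 and Dnajb1 0.067. Without a filter Hspa1a had 0.615 and Hspa1b 0.939, and Slc16a10 had 0.0844 in a fit of only those groups. Jun (6.89 ± 1.56, adjusted p = 0.0608), Dusp1 (4.20 ± 1.17, 0.148) and Fos (5.66 ± 1.59, 0.153) did not pass, nor did Cxcr6 (-1.36 ± 0.58, 0.458) or S1pr1 (-0.09 ± 0.45). Immediate early genes had a median of 3.37, with 13 of 30 passing, and 26 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.65e-50). NF-kB targets (median 1.52, 3 of 15, 11 adjusted over the list alone) and resident memory genes (median 0.88, 8 of 27, 11 adjusted over the list alone) had camera adjusted p of 2.89e-15 and 7.04e-14. All 3 held with an estimated correlation. Heat shock genes (median 2.17, 5 of 18, 12 adjusted over the list alone) had 3.19e-17 and adjusted p = 0.0994 with an estimated correlation. TGF-beta response genes (median 0.87, 1 of 11, 3 adjusted over the list alone) had 1.73e-05 and adjusted p = 0.0994 with an estimated correlation. The unfolded protein response (median 0.33, 0 of 19, 3 adjusted over the list alone) had 0.0234, and B cell markers (median -0.62, 0 of 8) had 0.0318 in the lower direction. Each of these last lists had adjusted p = 0.168 with an estimated correlation.

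The enzyme and the reducing agent, both used for 30 minutes at 37 °C, did not separate. Nr4a1 was at 3150.1 ± 50.5 CPM in collagenase and 1896.9 ± 928 CPM in DTE (0.73 ± 0.71), Cd69 at 942 ± 379 and 788 ± 61.8 CPM (0.26 ± 0.52), and Egr1 at 85.5 ± 41.5 and 191 ± 107 CPM (-1.16 ± 0.61). Between them 0 genes passed by edgeR and 0 by DESeq2, with 311 at an unadjusted p under 0.05 where chance gives 566. The same test on simulated counts recovered 42 of 50 genes changed 8-fold and 12 of 50 changed 4-fold, among 10794 genes. By camera, heat shock genes (median 0.66, 2.12e-06), NF-kB targets (0.58, 5.68e-05), resident memory genes (0.44, 3.03e-05), TGF-beta response genes (0.69, 0.000128) and myeloid markers (1.02, 0.00101) were higher in collagenase, and cytokines lower (-0.44, 0.0218). None held: in the same order, adjusted p = 0.544, 0.325, 0.197, 0.319, 0.63 and 0.678 with an estimated correlation.

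In kidney, where cells cannot be had without digestion, collagenase again raised the immediate early genes over CAP. Nr4a1 was at 1177.8 ± 38.8 CPM against 5.4 ± 3.58 CPM (7.69 ± 0.97), and Nr4a3 at 427 ± 187 against 6.14 ± 5.64 CPM (6.02 ± 0.74). Nr4a2 was higher by a ratio of 276 (94.3 to 1343) over low counts. Klf4 and Egr3, without counts in CAP, were at least 53.9-fold and at least 46.4-fold higher. Egr1 rose from 11.4 ± 3.09 to 759 ± 518 CPM (6.06 ± 0.76). Kidney cells in collagenase also held more RNA of effector cytokines, which memory T cells release within hours of restimulation. Ccl3 (chromosome 11, 83647844 to 83649355) was at 911 ± 705 CPM against 27.5 ± 30.8 CPM (5.01 ± 0.88, adjusted p = 0.0319). Its neighbour Ccl4 was at 2612.9 ± 1755.3 CPM against 168 ± 129 CPM (3.96 ± 0.66, adjusted p = 0.0215), and Tnf at 277 ± 80.7 against 36.5 ± 9.22 CPM (2.93 ± 0.52, adjusted p = 0.0328). Ctla4 rose by 4.15 ± 0.56, Rgs2 by 3.67 ± 0.66 and Nfkbid by 2.88 ± 0.43. Cd69 was at 1394.9 ± 969 CPM in collagenase and 176 ± 37 CPM in CAP (2.99 ± 0.56, adjusted p = 0.0484).

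Collagenase against CAP in kidney gave 24 genes, 23 higher and 1 lower, the lower being the predicted gene Gm26724, named after its values were seen. The count became 16 without collagenase replicate 1, 36 without collagenase replicate 3, 15 without CAP replicate 1 and 7 without the unnumbered CAP library. Nr4a2, Nr4a3, Klf4 and Egr1 passed in each of those fits. Without the unnumbered CAP library, Ccl4 had an adjusted p of 0.193, Ccl3 0.147, Tnf 0.193 and Cd69 0.462. Without collagenase replicate 1, the same genes had 0.0656, 0.0827, 0.104 and 0.287. Without CAP replicate 1, Tnf had 0.323, Cd69 0.165, Egr3 0.11, Nfkbid 0.0717 and Rgs2 0.0545. Rgs2 had 0.364, Nfkbid 0.151, Egr3 0.139 and Ctla4 0.0959 without the unnumbered CAP library, and Rgs2 had 0.125 without collagenase replicate 1. In a fit of only those groups, Cd69 had 0.747, Ccl4 0.51, Ccl3 0.286, Tnf 0.285, Nfkbid 0.251, Rgs2 0.244 and Ctla4 0.0569. Cd69 had 0.0573 with DESeq2-style size factors and 0.0595 with the stricter filter, where Rgs2 had 0.055, and Ccl3 had 0.0999 with the Gm10800 covariate. Fos (8.63 ± 1.80, adjusted p = 0.0928), Dusp1 (5.55 ± 1.24, 0.15), Jun (5.85, 0.312) and Hspa1a (119 ± 10.9 against 0.358 ± 0.507 CPM, 0.229) did not pass. Cxcr6 changed by 0.27 ± 0.57, Itga1 by -0.28 ± 0.56, and S1pr1 by -0.00 ± 0.46, with Xcl1 at 1.52 ± 0.57, and none passed.

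Immediate early genes in kidney had a median of 3.74, with 12 of 30 passing and 24 adjusted over the list alone (camera adjusted p = 9.44e-116). Resident memory genes (median 0.73, 4 of 27, 8 adjusted over the list alone) had 9.46e-20, and cytokines (median 2.20, 3 of 10, 6 adjusted over the list alone) had 3.83e-19. Those calls held with an estimated correlation. NF-kB targets (median 0.56, 1 of 15, 4 adjusted over the list alone) had 1.82e-09 and adjusted p = 0.0713 with an estimated correlation. Heat shock genes (median 0.55, or 0.62 with bounds, 0 of 18, 4 adjusted over the list alone) had 4.09e-09 and adjusted p = 0.226 with an estimated correlation. Unfolded protein response genes (0.28), TGF-beta response genes (0.51, 1 adjusted over the list alone) and cell cycle genes (0.62) had 0.0189, 0.0189 and 0.0356, becoming adjusted p = 0.195, 0.287 and 0.262 with an estimated correlation. Myeloid markers were lower in collagenase by a median of -1.84, with 0 of 15 passing over all genes or adjusted over the list alone (camera adjusted p = 7.36e-10, adjusted p = 0.17 with an estimated correlation). Natural killer markers, which share Fcer1g and Tyrobp with that list, had a median of -1.04 (0.0246, adjusted p = 0.249 with an estimated correlation).

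**Figure D3:**
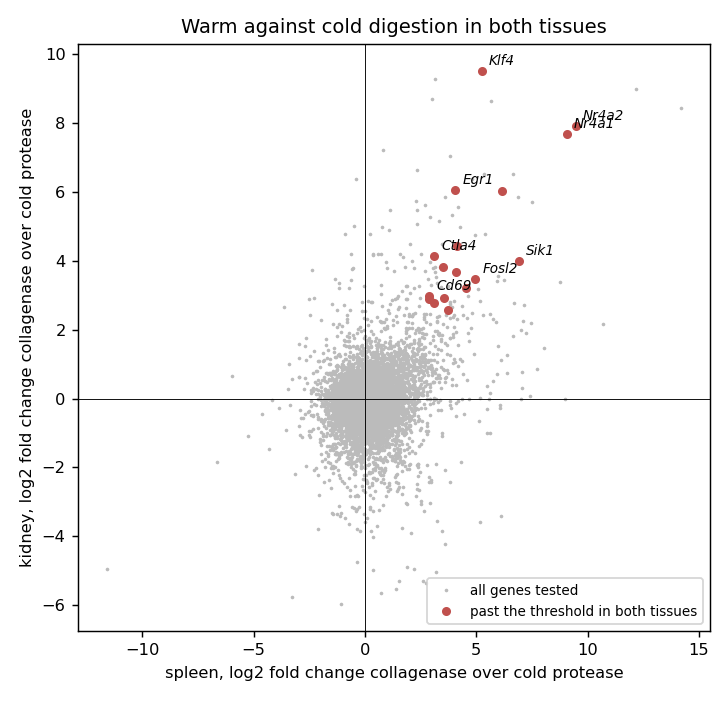
Log2 fold change of collagenase over CAP in spleen on the horizontal axis and in kidney on the vertical axis for the 11329 tested genes in grey, with the 17 genes past the threshold in both tissues in red. All 17 lie in the upper right quadrant.

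The difference between warm collagenase and cold CAP was shared between tissues, from libraries with no overlap. Temperature and enzyme changed together in both tissues, so the sharing does not show which of them caused it. No group was held warm without collagenase or DTE. Of the 94 genes higher in spleen and 23 higher in kidney, 17 were the same, against 0.191 for independent lists. The 17 became 6 without spleen CAP replicate 1, 5 without spleen CAP replicate 3, 10 without kidney CAP replicate 1 and 7 without the unnumbered kidney CAP library. They were Nr4a1, Nr4a2, Nr4a3, Sik1, Klf4, Fosl2, Kdm6b, Ppp1r15a, Rgs2, Egr1, C920009B18Rik, Cxcr4, Gadd45b, Dusp5, Ctla4, Nfkbid and Cd69. Of 96 spleen calls, 94 had the same sign in kidney, and 23 of 24 kidney calls had the same sign in spleen. Across all genes, which are not independent replicates, the Pearson correlation was 0.264 and the Spearman correlation 0.0611. Pearson's value was 0.0129 without kidney collagenase replicate 3, 0.0423 without kidney CAP replicate 1, 0.147 without spleen collagenase replicate 3 and 0.166 without spleen CAP replicate 1.

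Whether the tissues responded differently was tested by the interaction of tissue and digestion, where 0 genes passed by edgeR and 6 by DESeq2. With all libraries 439 had an unadjusted p under 0.05 where chance gives 566. The number lay above chance, for the genes tested in each fit, when kidney CAP replicate 1 or kidney collagenase replicate 3 was left out. For Cd69 the interaction was 0.12 ± 0.73, for Nr4a1 -1.37 ± 1.13, for Egr1 2.01 ± 0.96, for Cxcr6 1.63 ± 0.81 and for Hspa1a -5.75 with a 95% interval from -17.43 to 5.94. The test is less sensitive than the others, and on simulated counts it recovered 18 of 50 genes changed 8-fold and 44 of 50 changed 32-fold, among 10768 genes. Cytokines rose more in kidney (median 1.16, camera adjusted p = 5.47e-07), with Ccl3 and Ccl4 past the threshold adjusted over the list alone and 0 of 10 over all genes. Myeloid markers were lower (median -2.18, 8.36e-07), with Adgre1, C1qa, Cd74, C1qb and Csf1r adjusted over the list alone and 0 of 15 over all genes. Heat shock genes (median -1.02, 0.000497) and NF-kB targets (median -0.82, 0.000578) rose less in kidney. None of the 4 held: cytokines, myeloid markers and NF-kB targets had adjusted p = 0.508 with an estimated correlation, and heat shock genes 0.622. The myeloid list had 0.108 without kidney collagenase replicate 3, and the NF-kB list 0.0867 without spleen collagenase replicate 3. The immediate early list (median 0.07) had a camera adjusted p of 0.672.

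Kidney and spleen cells were compared within each enzyme, which asks what distinguishes the tissues at equal digestion. Residency cannot be told apart here from tissue or from RNA of other cells. In collagenase, kidney cells had more Xcl1, a chemokine gene of resident cells (chromosome 1, 164931644 to 164935527), with 229 ± 172 against 6.05 ± 0.228 CPM (5.23 ± 0.70, adjusted p = 0.0183). Zfp683, encoding the resident memory regulator Hobit, was higher by 4.01 ± 0.71, P2rx7 by 5.34 ± 0.93, Qpct by 4.50 ± 0.60 and Ly6g5b by 4.77 ± 0.72. Ccl3 (5.51 ± 0.90) and Ccl4 (3.89 ± 0.66) were higher in kidney as well. The iron exporter gene Slc40a1, without counts in kidney collagenase, was at least 46.5-fold lower. Nsg2 fell by 3.21, Pogk by 2.76 and Cmah by 2.69 on the log2 scale. Lzts1 (3.70), Ckb (3.64), Eif4e3 (2.55) and the predicted gene Gm20743 (6.67) were also among the 16 called genes, 11 higher and 5 lower. Cxcr6 at 2890.0 ± 1297.4 against 332 ± 135 CPM (3.12 ± 0.62, adjusted p = 0.0847), S1pr1 (-1.85 ± 0.47, 0.219) and Itga1 (2.16 ± 0.59, 0.246) did not pass, nor did Cd69 (0.57 ± 0.52, 0.68), Itgae (-0.63 ± 0.71) or Klf2 (-0.79 ± 0.68). The 16 became 0 without spleen collagenase replicate 1, 0 without spleen collagenase replicate 3, 0 without kidney collagenase replicate 1 and 39 without kidney collagenase replicate 3, where Cxcr6 passed at 0.0281 and Nsg2 had 0.0612. With the stricter filter Ccl4 and P2rx7 had 0.0517 each and Zfp683 0.0646, and with the Gm10800 covariate Ccl3 had 0.0548.

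In collagenase the circulating memory list was lower in kidney by a median of -1.43, with 2 of 29 passing and 13 adjusted over the list alone (camera adjusted p = 1.96e-14, held with an estimated correlation). Resident memory genes were higher by 0.68, with 3 of 27 passing, and 9 higher and 1 lower adjusted over the list alone (7.24e-07, adjusted p = 0.0587 with an estimated correlation). Cytokines were higher by 1.59, with 3 of 10 passing and 6 adjusted over the list alone (7.13e-11, adjusted p = 0.121 with an estimated correlation). Heat shock genes were lower by a median of -1.38, with 0 of 18 passing and 10 adjusted over the list alone (1.01e-09, adjusted p = 0.239 with an estimated correlation). NF-kB targets were lower (-0.96, 6.19e-05, adjusted p = 0.238 with an estimated correlation). Kidney epithelium markers (2.24 over 3 tested genes, 0.00912), T cell identity genes (0.45, 0.0138) and interferon-stimulated genes (0.67, 0.0298) were higher, with adjusted p = 0.239, 0.447 and 0.276 with an estimated correlation.

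With both tissues in CAP, 0 genes passed by edgeR and 38 by DESeq2. With all libraries 456 had an unadjusted p under 0.05 where chance gives 566. Xcl1 was at 79.6 ± 51.8 CPM in kidney and 5.06 ± 1.3 CPM in spleen (3.97 ± 0.67, adjusted p = 0.0963). All 16 genes called in collagenase had the same sign in CAP. Estimates in CAP were 0.03 for Ccl3, 0.88 for Ccl4 and -1.04 for Slc40a1, each with an adjusted p of 1, and -1.35 for Nsg2, -1.23 for Pogk and 1.36 for Eif4e3. P2rx7 (5.00), Ckb (4.06), Ly6g5b (3.97), Zfp683 (3.18) and Qpct (2.98) had adjusted p between 0.0963 and 0.168. Selection in collagenase alone favours large estimates in collagenase, while those in CAP come from other libraries. The difference between enzymes was tested only by the interaction, where 0 genes passed by edgeR and 6 by DESeq2. There 439 had an unadjusted p under 0.05 where chance gives 566. Cd69, at 176 ± 37 CPM in kidney and 129 ± 7.42 CPM in spleen, did not pass (0.45 ± 0.52). S1pr1 (-1.93 ± 0.47, 0.356), Itga1 (2.49 ± 0.60, 0.353), Cxcr6 (1.49 ± 0.58, 0.983) and Klf2 (-1.10 ± 0.70, 1) did not pass. Across genes the tissue differences in the 2 enzymes had a Pearson correlation of 0.241 and a Spearman correlation of 0.169. Pearson's value was -0.0035 without kidney CAP replicate 1, 0.0906 without spleen CAP replicate 1 and 0.158 without spleen collagenase replicate 3. Whether any gene passed by edgeR depended on which library was left out, also for libraries outside the groups compared.

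In CAP, 5 of the 20 tested lists were called by camera between tissues, and 2 of these held with an estimated correlation. Circulating memory genes were lower in kidney by a median of -1.07, with 0 of 29 passing and 10 adjusted over the list alone (camera adjusted p = 5.72e-24). Resident memory genes were higher by a median of 1.03, with 0 of 27 passing, and 13 higher and 1 (Ctla4) lower adjusted over the list alone (6.35e-20). Those calls held with an estimated correlation. Myeloid markers were higher by 2.49, with 7 of 15 adjusted over the list alone (9.99e-10, adjusted p = 0.184 with an estimated correlation). B cell markers were lower by a median of -1.45, with 2 adjusted over the list alone (0.000398, adjusted p = 0.0793 with an estimated correlation). Kidney epithelium markers were higher by 3.45, or 2.01 with bounds, and Gpx3 and Kap passed adjusted over the list alone (0.000827, adjusted p = 0.128 with an estimated correlation). Cytokines had a median of 0.39 and a camera adjusted p of 0.193.

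**Figure D4:**
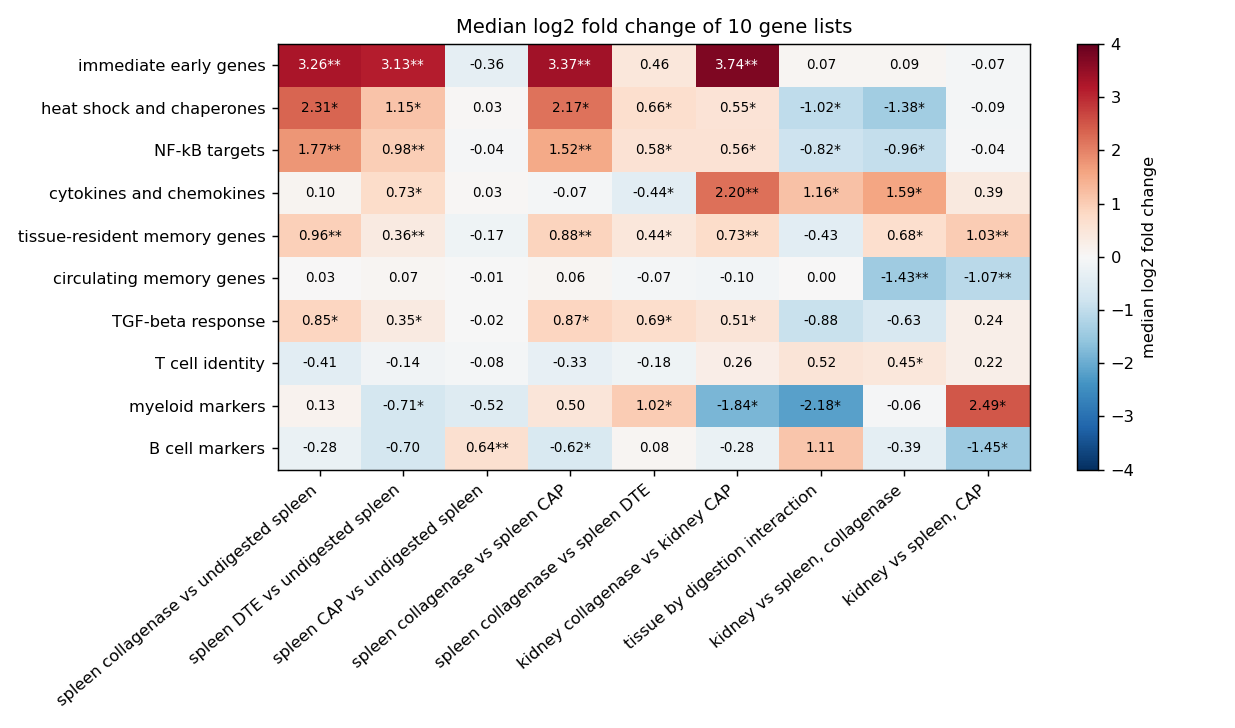
Median log2 fold change of 10 gene lists (vertical) in the 9 comparisons (horizontal), on a color scale from -4 to 4. A star marks a camera adjusted p under 0.05 and a second star a call that held with an estimated correlation; the immediate early list has a median of 3.26 in spleen collagenase and 3.74 in kidney.

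RNA of other cells was measured alongside. Summed myeloid markers reached 1218 ± 510.2 CPM in kidney CAP, against 541 ± 380.4 CPM in kidney collagenase, 425 ± 8.87 CPM in spleen CAP and 376 ± 129 CPM in spleen collagenase. The B cell markers summed to 303 ± 169 CPM in kidney CAP and 217 ± 27.9 CPM in spleen CAP. Kidney epithelium markers stood at 30.5 ± 17.8 CPM in kidney CAP, 36.9 ± 9.99 CPM in kidney collagenase and 9.75 ± 0.257 CPM in spleen CAP. Too few genes were tested for 3 lists. CD4 T cell markers (2 tested) summed to 55.2 ± 4.71 CPM in kidney collagenase and 32 ± 7.72 CPM in kidney CAP. In spleen they summed to 25.5 ± 3.48 CPM in collagenase, 22.5 ± 8.43 CPM in DTE, 9.13 ± 0.0458 CPM in CAP and 16 ± 4.24 CPM in undigested cells. Endothelial and stromal markers (1 tested) summed to 30.4 ± 26.1 CPM in kidney collagenase and 33.4 ± 15.5 CPM in kidney CAP. Erythroid and platelet markers (2 tested) summed to 301 ± 412 CPM in spleen CAP, nearly all from replicate 3. Oxidative stress, cold-induced RNA-binding, glycolysis and hypoxia, cholesterol synthesis and cytotoxic effector genes were called in none of the 9 comparisons, with smallest camera adjusted p of 0.523, 0.491, 0.395, 0.492 and 0.159. Mitochondrial genes held 2.75% to 5.95% of counts and ribosomal protein genes 3.71% to 8.48%, and CT010467.1 alone held 6.90% to 24.1%. Between spleen collagenase and CAP the mitochondrial share (4.38 ± 0.00937% against 5.22 ± 0.19%) and the CT010467.1 share (14.6 ± 1.13% against 18.2 ± 0.734%) did not overlap. Nor did total counts, the hemoglobin share or summed natural killer markers (150 ± 49.3 against 228 ± 24.1 CPM). Summed B cell, CD4 T cell, erythroid and platelet, and endothelial and stromal markers did not overlap either. The two-sided exact permutation p of 0.333 is the smallest possible with 2 libraries per group and decides nothing.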

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

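All tests in this part of why lists differed were chosen only after the result was seen. A test of the difference itself drew attention to 4 gene lists whose collagenase against CAP effect differed between kidney and spleen by camera. These were cytokines and chemokines (adjusted p = 5.47e-07), myeloid markers (8.36e-07), heat shock genes (0.000497) and NF-kB targets (0.000578). All 4 ended with an estimated correlation, at 0.508 for cytokines, myeloid markers and NF-kB targets and 0.622 for heat shock genes. With fry each had 0.523.

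Cytokine and chemokine genes differed more between collagenase and CAP in kidney than in spleen. Ccl3 reached 1409 and 412 CPM in the kidney collagenase libraries and 12.3 to 27.4 CPM in the spleen collagenase libraries. A single library carrying the difference is argued against, since the list's highest adjusted p over the 8 fits without 1 library was 0.00371, without spleen collagenase replicate 3. A property that goes with the share of Gm10800 counts is argued against as the whole cause, also only at the preset correlation. With that covariate the camera adjusted p was 0.000118. A difference between resident and circulating cells in how they respond to warm digestion may account for it and was not tested. RNA from other kidney cells remains open as well.

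Myeloid markers were higher in kidney CAP than in kidney collagenase by camera (adjusted p = 7.36e-10), adjusted p = 0.17 with an estimated correlation, with 0 of 15 passing over all genes or adjusted over the list alone. Cd74 was at 178 and 221 CPM in the CAP libraries and at 59.7 and 17.5 CPM in the collagenase libraries, and H2-Aa at 291 and 130 against 96.5 and 18 CPM. Of 15 tested markers, 9 were higher in both CAP libraries than in both collagenase libraries, which restates the pattern and does not test its source. Summed over the list, the CAP libraries were at 1579 and 858 CPM and the collagenase libraries at 810.3 and 272 CPM. RNA of myeloid cells in the CAP libraries stays open, and 2 of the list's genes, Fcer1g and Tyrobp, are also natural killer markers. For collagenase against CAP in kidney a single library is argued against, since the highest adjusted p at the preset correlation over the 4 fits without 1 kidney library was 0.0111, without kidney collagenase replicate 3. For the difference between tissues a single library is not excluded, since the list had 0.108 without kidney collagenase replicate 3.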

How the results depend on the processing

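Tests added only after results were seen were those with the Gm10800 covariate and without CT010467.1, mt-Rnr2, Gm10800 and Gm10801. The other alternatives were set beforehand. Called counts of genes stayed within 1.5 times their value with DESeq2-style size factors, with the stricter filter and without those 4 genes, in all 9 comparisons. In the order spleen collagenase, DTE and CAP against undigested, collagenase against CAP in spleen, collagenase against CAP in kidney, interaction, kidney against spleen in collagenase and in CAP, the counts of 82, 25, 0, 96, 24, 0, 16 and 0 became 176, 80, 3, 201, 70, 11, 116 and 51 without a filter. With DESeq2 they became 183, 67, 0, 212, 69, 6, 112 and 38. A fit of only the groups compared gave 214, 100, 0, 359, 10, 0, 113 and 11, and the Gm10800 covariate 218, 58, 0, 244, 54, 1, 148 and 70. Collagenase against DTE stayed at 0 in each. For kidney against spleen in collagenase the 11 higher and 5 lower genes became 57 and 59 without a filter, 59 and 53 with DESeq2, 51 and 62 with only those groups and 74 and 74 with the covariate. The cause was not tested.

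The labels do not say that replicate numbers pair these samples, and they were not used as pairs. Deviations of same-numbered libraries correlated between -0.45 and 0.42 over 10 pairs of groups, 4 of them over 0.1 and 4 under -0.1. Undigested spleen correlated at 0.42 with both spleen collagenase and spleen CAP, and these at 0.32 with each other. Spleen DTE did not follow, at -0.15 with undigested spleen, 0.06 with spleen collagenase and -0.01 with spleen CAP. It correlated at 0.34 with kidney collagenase instead. A shared origin of same-numbered spleen samples stays open, though the DTE values do not point to it. With the number as a block, on the 11 numbered libraries, the counts were 98, 34, 1, 133, 7, 0, 32 and 0 in the order above. For kidney collagenase against CAP the block leaves CAP with 1 library. The calls of Nr4a1, Egr3, Ccl3, Ccl4, Tnf, Cd69, Rgs2, Nfkbid and Ctla4 ended there. Their log2 changes under the block were 7.51, 9.03, 4.42, 3.38, 3.39, 2.86, 3.09, 3.01 and 3.66 in that order. Cd69 had 0.052 under the block in collagenase against undigested spleen. List counts moved under the block only for the interaction, from 4 to 7. The cause was not tested.

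Leaving out 1 library of the groups compared leaves its group with 1, assumed to vary like the others. Counts then ran from 7 to 31, 0 to 16, 0 to 0, 6 to 48, 7 to 36, 0 to 2, 0 to 39 and 0 to 2. Counts of called lists ran from 5 to 7, 6 to 8, 1 to 5, 6 to 6, 8 to 9, 3 to 6, 7 to 9 and 4 to 7, and for collagenase against DTE from 2 to 8. Direction reversed for 3 list results: myeloid markers in DTE against undigested spleen without undigested replicate 3 (0.572), the same list in CAP against undigested spleen without undigested replicate 3 (0.0123), and immediate early genes in CAP against undigested spleen without undigested replicate 1 (0.00521). Over all fits without 1 library, the adjusted p of myeloid markers ran from 5.28e-05 to 0.913 in DTE against undigested spleen and from 0.0011 to 0.887 in CAP against undigested spleen. For immediate early genes in CAP against undigested spleen it ran from 1.5e-08 to 0.535. The cause was not tested.

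For the lists, 6, 9, 2, 7, 10, 4, 8 and 5 were called by camera in the same order and 6 for collagenase against DTE. With an estimated correlation these were 3, 3, 1, 3, 3, 0, 1 and 2, and 0 for collagenase against DTE. Directional fry called 6, 3, 0, 6, 2, 0, 2 and 2, and 0 for collagenase against DTE. Mixed fry called 6, 4, 0, 8, 4, 0, 9 and 3, and 0. The stricter filter gave 3 lists for kidney against spleen in CAP. The cause was not tested.

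Over the alternatives other than leaving out 1 library, named gene results kept direction and side of the threshold in 1350 cases, were newly past it in 49 and no longer past it in 43. For lists these were 1474, 21 and 94. Without 1 library, 622 gene results were kept, 156 no longer passed and 6 newly passed. The kept results in these tallies include those past the threshold in neither fit, whatever their direction. Only results past it in the main fit could stop passing, so the tallies do not give the share of calls that held. Depth of 1199423 to 2700518 counts per library limits what can be said of genes near the floor of 3 counts.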

Other observations

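In this part every test was chosen only after the result was seen, except the overlap of the digested kidney genes with the spleen genes. Across the 4 comparisons with a called warm treatment, which share libraries, 13 genes rose in each, 3 of them in no list: Kdm6b, Cxcr4 and C920009B18Rik. Without undigested replicate 3, DTE called 0 genes, so that count was 0. The genes in this paragraph were chosen after their values were seen. Kdm6b, a demethylase of histone H3 lysine 27, rose by 4.49 in spleen collagenase, 3.60 in DTE, 4.53 in collagenase against CAP in spleen and 3.20 in kidney. Cxcr4, a homing receptor, rose by 2.97, 2.64, 3.57 and 2.93 in the same order. Irf4, which T cells raise with receptor signal strength, rose by 5.72 in spleen collagenase and by 3.96 in DTE, and reached 3.45 in kidney without passing there (adjusted p = 0.0755). Of the 82 genes of spleen collagenase, 54 were in no list, among them Per1 (3.11), Odc1 (3.29), Tgif1 (4.19) and Bcl2l11 (3.01).

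A comparison of kidney in collagenase with undigested spleen mixes tissue with handling. It gave 61 genes, 49 higher and 12 lower, and 10 resident memory genes were among those higher, with a list median of 2.55. Kidney in CAP against undigested spleen gave 1 gene, lower, by edgeR, and a resident memory median of 0.93. There 446 genes had an unadjusted p under 0.05 where chance gives 566. A hypothesis set before that overlap was seen was that warm digestion adds genes to the first comparison. Of its 49 higher genes, 26 were also higher in collagenase than in CAP in spleen, in other libraries, where independent lists share 0.407 (Fisher's exact test, one-sided, p = 8.98e-43). Fisher's test treats genes as independent, which they are not, and both lists came from 1 model fit. The overlap fits the hypothesis, but it does not tell warmth from collagenase, which was used only warm. Nr4a1 showed 7.03 with collagenase and -0.66 with CAP, and Cd69 3.17 and 0.18. Xcl1 showed 6.11 and 4.59, P2rx7 5.12 and 5.06, and Krt83 6.69 and 6.38.

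Some immediate early genes had counts in undigested spleen replicate 1 and almost none in replicate 3, while the list summed to 1779 and 1092 CPM. Fos was at 71.7 and 0 CPM, Jun at 106 and 0 CPM and Nr4a1 at 16.4 and 1.34 CPM. Carry-over from a library digested at 37 °C could give such counts. Nr4a1 made up 18.7% of Nr4a1 plus Fos counts in replicate 1 (exact binomial 95% interval 13.6% to 24.6%), below the lowest share of 36.2% among the 6 libraries digested at 37 °C. As the only source of the Nr4a1 and Fos counts, carry-over from any 1 of them is argued against by the upper bound of 24.6%. That interval covers counting error only. Carry-over beside Fos RNA of the sample's own is not excluded, since own Fos counts lower the share.

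The first principal component, with 34.1% of the variance, went with the share of Gm10800 counts across the 12 libraries. Pearson's r was -0.738 (permutation p = 0.0073) and Spearman's rho -0.748 (permutation p = 0.0068), and r was -0.797 without the 2 libraries farthest from the median share. This was the only relation computed in its family. Gm10800 held 0.419% to 10.2% of counts. Hemoglobin genes held 0.0569% of counts in spleen CAP replicate 3, where Hbb-bs was at 367 CPM, against 3.31 CPM in spleen CAP replicate 1.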
